A study of Dendrobium nobile and Dendrobium officinale with 3 samples.

How the data were processed

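Small RNA was sequenced from 3 libraries, 1 from each of 3 groups: protocorms of Dendrobium nobile, leaf of D. nobile, and protocorms of D. officinale. Per the labels' protocols, protocorms were cultured on a medium with 6-BA and NAA and collected after 30 days, and the leaf came from a plant about 4 years old. RNA was extracted with a miRNeasy kit, libraries were made with the TruSeq small RNA kit, and library bands of a narrow size range were cut from a gel. The size cut restricts which insert lengths could be sequenced. The submitters' processing notes name bcl2fastq 1.8.4. The adapter trimmer, the read mapper and the genome build are not given in the sources used here.

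The authors deposited a table of 461 miRNA arms with an RPM value for each library, that is, reads scaled to a common library size. The authors also deposited the output of a miRNA predictor, miRDeep2 per the file headers, for 384 precursors. That table gives each precursor's score as deposited by the authors, read counts pooled over the libraries (total, mature, loop and star, per the file headers), the sequences of both arms, the precursor sequence and its coordinates. The start in that table counts from 0 and is given here counted from 1. All 461 arms were found among the 768 arms of the predictor's table, and the other 307 were not in the expression table.

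The RPM values have 2 decimals and are whole multiples of the value of 1 read, so the reads could be recovered. A library total was searched for which every value above 0 gives a whole number of reads within the rounding of the file. A single total fitted each library, and 100% of the values came out whole. The totals were 2842760 reads for the D. nobile protocorm, 1261144 for the D. nobile leaf and 1425154 for the D. officinale protocorm. The listed arms fell short of these totals by 60, 46 and 27 reads. One read was worth 0.352, 0.793 and 0.702 RPM. How reads that fit several arms were assigned is not given in the sources used here. Of the 461 arms, 133 share their sequence with another, in 59 repeated sequences. The copies had the same reads in 28 of these, reads within 5% or 3 reads of each other in 13, and reads further apart in 18, so that these totals are not known to count each read once. With the copy with most reads kept for each sequence, the 387 distinct sequences hold 63.6%, 64.3% and 68.7% of the totals.

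The names den_miR1 to den_miR384 are serial numbers of the authors and not miRNA family numbers, so that den_miR156 is not miR156. Families were therefore assigned by sequence. Each arm was compared without gaps with hand-written canonical sequences of 44 plant families, and was taken as a member with at most 3 mismatches over at least 18 nt or at most 1 over at least 15 nt. This gave 65 known arms in 22 families. A further 43 arms are the opposite arm of a precursor with a known arm or have the sequence of one, and the remaining 353 are called predicted new arms here. Members of miR159 and miR319 are similar in sequence. den_miR74-3p was assigned to miR319 with an uncertain call.

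With 1 library per group no test, p-value or standard error is possible, and differences have no replicate check. The rule fixed for a count table was not the main rule, because the values deposited are RPM. It could still be run on the recovered reads, as an alternative added after seeing the data. It called fewer new arms higher and fewer lower in each comparison. The fallback fixed for normalized values was used: an arm or family was called higher or lower when it reached 10 RPM in 1 of the 2 libraries and its log2 ratio, on the scale of log2(RPM + 1), was at least 1 in size. The pseudocount of 1 understates the change of low arms. Fold changes are ratios of RPM with exact 95% conditional binomial intervals, shares have exact Clopper-Pearson 95% intervals, and levels have exact Poisson intervals. These cover counting error only, since reads amplified by PCR are not independent molecules and no biological spread was measured. Where a library had no read, a floor of 3 reads in that library gives a lower bound. Family values are sums over the listed members, while ratios of opposite arms count each distinct sequence once.

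For each of 10 lists of families fixed before the data were examined, the median log2 ratio was set against 10000 random lists of the same size, drawn from the 40 features nearest in mean expression to each member. These features are mostly predicted new arms, 203 of 254 for the leaf against the D. nobile protocorm and 163 of 206 for the 2 protocorm libraries, so that this percentile also reflects how known families differ from new arms. A second percentile, chosen after seeing the data, sets the list among all sets of the same size of the known families alone, not matched on expression. Both describe these libraries. The items named in the text were taken from these, per comparison: the 10 families with the largest and the 10 with the smallest log2 ratio, any fixed-list family above the minimum, the 5 families with most reads in each library, the 5 known and 5 new arms with the largest ratio in each direction past the rule, and the 5 new arms with most reads in each library. Precursors were folded with RNAfold 2.7.2.

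Alternatives were edgeR 4.0.16 TMM factors and DESeq2 1.42.0 median-of-ratios factors computed on the recovered reads, totals without the most abundant family, other minimums, pseudocounts of 0.1 and 10, a log2 ratio of 2, identical sequences or family members counted once, the most abundant member of a family alone, and score minimums of 5 and 10. Chosen after seeing the data were a count rule on the recovered reads (at least 50 reads and a counting interval beyond 2-fold), arms with nearly the same counts (within 5% or 3 reads) counted once, totals and calls without arms under 18 nt, totals without the most abundant new arm, and the scaling, ratio and pseudocount alternatives for the new arms. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.

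The size rule was tested on simulated Poisson counts of the 461 arms with 200 arms changed. All rates are over simulated arms that reached the minimum of 10 RPM, so changed arms under it, which the rule missed, are left out. For the leaf against the D. nobile protocorm the rule recovered 93.0% of 43 such arms raised 3-fold and 96.7% of 30 lowered 3-fold. It called 1.20% of 167 unchanged arms. In the same simulation 95.7% of the intervals held the simulated fold. For the 2 protocorm libraries the rule recovered 100% of 44 such arms raised 3-fold and 87.9% of 33 lowered 3-fold. Simulation covers counting error and no variation between plants.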

Results

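The study sequenced small RNAs of Dendrobium, a genus of orchids, to learn about the function of miRNAs in these plants, with dendrobine biosynthesis in D. nobile named in its title. A protocorm is the small tuber-like body that a germinating orchid seed forms before it makes a shoot. There was 1 library for each of 3 groups: D. nobile protocorm, D. nobile leaf and D. officinale protocorm. The recovered totals were 2842760, 1261144 and 1425154 reads over 461 miRNA arms, so that 1 read was worth 0.352, 0.793 and 0.702 RPM. No group had a replicate. All intervals are 95% intervals that cover counting error only, apart from bootstrap intervals, which show the spread over arms. Family sums may count reads of repeated copies more than once, which the intervals do not cover.

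Known families held most of the listed reads in each library: 63.5% in the D. nobile protocorm, 63.3% in the leaf and 56.9% in the D. officinale protocorm. miR166, which targets HD-ZIP III transcription factors of leaf polarity, was the most abundant family in all 3 libraries. It took 29.9% of reads in the D. nobile protocorm (Clopper-Pearson interval 29.8 to 29.9%), 28.13% in the leaf (28.05 to 28.21%) and 22.8% in the D. officinale protocorm (22.7 to 22.8%). Its mature sequence, UCGGACCAGGCUUCAUUCCCC, was listed from 2 loci, den_miR200-3p on NW_018267255.1 (197713 to 197825, minus strand) and den_miR281-5p on NW_018277045.1 (48611 to 48656, minus strand). The genome build is not given in the sources used here, and no gene annotation was used. With every repeated sequence counted once, in miR166 and in the totals alike, the miR166 shares were 27.1%, 23.6% and 19.03%. These are shares of smaller totals, which hold 63.6%, 64.3% and 68.7% of the full ones. They therefore do not show how far the shares of the full totals rest on the repeated copy. In the D. nobile protocorm miR156 (16.5%), miR319 (5.28%), miR396 (3.73%) and miR162 (3.66%) followed. In the D. officinale protocorm the order was miR156 (18.3%), miR162 (5.55%), miR319 (5.52%) and miR396 (1.84%). In the leaf miR396 (20.1%), miR162 (6.83%), miR168 (3.40%) and miR399 (1.68%) followed. The shares of these other families sum all listed copies. miR156 has 2 distinct sequences in 6 members, miR319 2 in 5, miR396 2 in 4, miR162 1 in 2 and miR168 3 in 5. Their size and order may therefore rest in part on reads counted more than once.

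**Figure D1:**
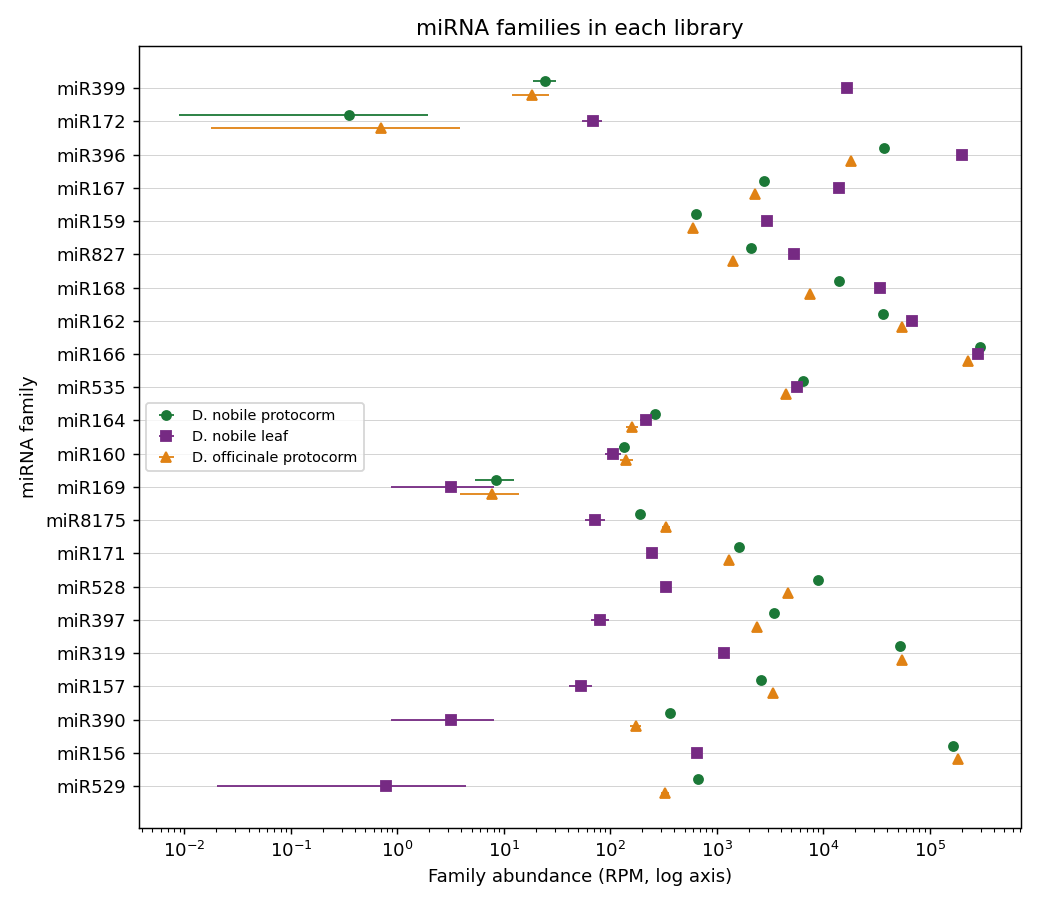
Abundance of the 22 miRNA families in RPM on a log axis, with 1 point per library and exact 95% Poisson intervals as bars, ordered by the leaf to D. nobile protocorm ratio. Both protocorm libraries lie close together for most families, whereas miR156 was at 165039 and 182683 RPM in the protocorms and 657 RPM in the leaf, and miR399 at 24.3 and 18.3 RPM in the protocorms and 16767 RPM in the leaf.

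The leaf was compared with the protocorm of the same species. miR156, which represses the SPL transcription factors that promote the adult phase, was 251-fold lower in the leaf (interval 235 to 269), at 657 RPM against 165039 RPM. miR156 has 6 listed members but 2 distinct sequences, so its sums may count reads more than once, which the interval does not cover. Across the alternatives its log2 ratio ran from -8.67 to -7.88. Its relatives miR157 and miR529 were also lower: miR157 by 49.0-fold (38.5 to 63.3), and miR529 with 1 read in the leaf against 663 RPM in the protocorm, an 839-fold difference (150 to 33030). miR172, which targets AP2-like factors and is known to rise as plants age, was higher in the leaf at 68.2 RPM against 1 read in the protocorm, a 195-fold ratio (33.9 to 7745). miR535 did not pass the rule, at 5717 RPM in the leaf and 6512 RPM in the protocorm. Of the 5 measured families of the age and phase change list, 1 was higher, 3 were lower and 1 was within the rule. The list's median log2 ratio of -5.59 lay at the 0.045 percentile of 10000 matched random lists, whose median was 0.99. These lists are drawn mostly from predicted new arms, whose own median was 0.99 against -0.28 for known families. Among all sets of 5 known families the list lay at the 1.75 percentile. Both percentiles count the related miR156, miR157 and miR529 as separate families, and the list's median is the value of miR157.

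Among the families of organ growth and polarity, miR396, which targets growth-regulating factors, was 5.40-fold higher in the leaf (5.36 to 5.44). miR159, which targets GAMYB-like factors, was 4.63-fold higher (4.38 to 4.90), at 2934 RPM against 633 RPM. The miR159 call rests on den_miR74-3p, an uncertain member, being counted in miR319. den_miR74-3p had 3421 RPM in the protocorm and no read in the leaf, so miR159 would not be higher with it included. miR319, which targets TCP factors, was 44.9-fold lower (42.7 to 47.3). miR166 and miR164 were within the rule, at log2 ratios of -0.09 and -0.28, but the most abundant member of miR164 taken alone was lower, at -2.32. The list's median of -0.09 lay at the 26.8 percentile of matched lists and the 69.2 percentile of known families. In the auxin pathway list, 1 of 4 measured families was higher, 1 was lower and 2 were within the rule. miR167, which targets auxin response factors, was 5.11-fold higher in the leaf (4.97 to 5.25). miR390, which triggers the trans-acting siRNAs against auxin response factors, was 114-fold lower (44.4 to 419), at 3.18 RPM against 362 RPM. miR160 was within the rule at a log2 ratio of -0.32, and just past it at -1.02 under median-of-ratios scaling. The median of this list, -0.30, lay at the 23.5 and 54.2 percentiles. miR393 had no listed arm.

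Of the nutrient-responsive families miR399, which targets the PHO2 regulator of phosphate uptake, was 691-fold higher in the leaf (546 to 888), at 16767 RPM against 24.3 RPM. miR827, another family of phosphate responses, was 2.51-fold higher (2.42 to 2.60), but was within the rule under TMM and median-of-ratios scaling, with a lowest log2 ratio of 0.62. The median of these 2 families, 5.35, lay at the 97.2 percentile of matched lists and the 97.9 percentile of sets of known families. Of the copper-responsive families miR397, which targets laccases, was 43.3-fold lower in the leaf (35.6 to 53.2), and miR528, which targets copper proteins in monocots, was 26.8-fold lower (24.3 to 29.6). Their median of -5.08 lay at the 1.14 percentile of matched lists, but at the 10.7 percentile among sets of 2 known families. miR398, miR408 and miR395 had no listed arm. miR171, which targets GRAS factors of the meristem, was 6.63-fold lower (5.91 to 7.46) as a sum, a log2 ratio of -2.72, and its most abundant member alone was lower at a log2 ratio of -5.69. In the meristem and flowering list 3 of 5 families had a listed arm. miR169 was under the minimum, and miR171 and miR172 differed in opposite directions, and the median of these 2, 1.48, lay at the 58.7 and 80.7 percentiles. miR168, which targets ARGONAUTE1, was 2.44-fold higher (2.40 to 2.47), and miR162, which targets DICER-LIKE1, was within the rule at a log2 ratio of 0.90. The median of this silencing list was 1.09, at the 56.1 and 77.4 percentiles. No family of the list that targets disease resistance genes had a listed arm. Of the list of entries suspected to be rRNA or tRNA fragments, miR8175 alone was listed, from a single arm, and was 2.66-fold lower in the leaf (2.12 to 3.35).

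In all, 7 families were higher in the leaf, 9 were lower and 5 were within the rule. The opposite arms of the same precursors, which are separate reads, differed in the same direction in 14 of the 14 called families that had one listed. The opposite arm of miR535, a family within the rule, was 26.1-fold higher in the leaf (15.1 to 48.8), unlike its matching arm. With each distinct sequence counted once, the miR156 opposite arms were 700.0-fold lower in the leaf (340 to 1741), or 917-fold (445 to 2281) summed over all listed copies, and the miR399 opposite arms were 277-fold higher (182 to 443). As single known arms, 19 were higher and 28 lower of 60 above the minimum, or 14 higher and 18 lower with identical sequences counted once. The arms with the largest ratios were den_miR207-3p and den_miR206-3p of miR399, at 5183 and 11318 RPM in the leaf and 5.28 and 18.3 RPM in the protocorm. Both lie on NW_018264589.1 on the minus strand, at 297720 to 297819 and 312388 to 312479, with den_miR220-3p of the same family at 284808 to 284907 on the plus strand. At the other end, den_miR74-3p, whose assignment to miR319 is uncertain, had no read in the leaf and 3421 RPM in the protocorm, at least 1438-fold lower. Its reads far exceed the predictor's mature reads for its precursor, given in the last paragraph, so this ratio is uncertain too. den_miR300-5p of miR156 was 399-fold lower. TMM and median-of-ratios scaling shifted all leaf to protocorm ratios by -0.38 and -0.70 on the log2 scale, and miR168 and miR827 were then within the rule. The other 14 called families kept their direction under every scaling.

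Of the predicted new arms, 118 were higher in the leaf and 51 lower among 237 above the minimum. The most abundant new arms were den_miR149-3p, den_miR221-5p, den_miR304-3p, den_miR59-3p and den_miR92-3p in the D. nobile protocorm, and den_miR330-3p, den_miR119-5p, den_miR149-3p, den_miR252-5p and den_miR2-3p in the leaf. den_miR221-5p and den_miR304-3p have nearly the same reads in each library, so they may not be separate. The largest ratio was that of den_miR170-3p (UGUCAUCGUUGUGGUCUUCUC), with 553 RPM in the leaf and 1 read in the protocorm, a 1581-fold ratio (281 to 62233). Its precursor lies on NW_018283516.1 at 124993 to 125121, minus strand. den_miR175-5p was 293-fold higher (142 to 731) and den_miR311-5p 122-fold higher (79.2 to 197). den_miR27-3p had 75.3 RPM in the leaf and no read in the protocorm, and den_miR13-3p had 2478 against 32.0 RPM. den_miR338-5p had 280 RPM in the protocorm and no read in the leaf, at least 118-fold lower. den_miR203-3p and den_miR137-3p had 53.5 and 33.4 RPM in the protocorm and also no read in the leaf, and den_miR117-5p was 61.0-fold lower. Arms of 15 to 17 nt, shorter than plant miRNAs, made up 64 of the arms higher and 28 of the arms lower. These counts rest on how many predictions are kept: with a predictor score of at least 5, 36 new arms were higher and 12 lower, and without arms under 18 nt 63 were higher and 20 lower.

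**Figure D2:**
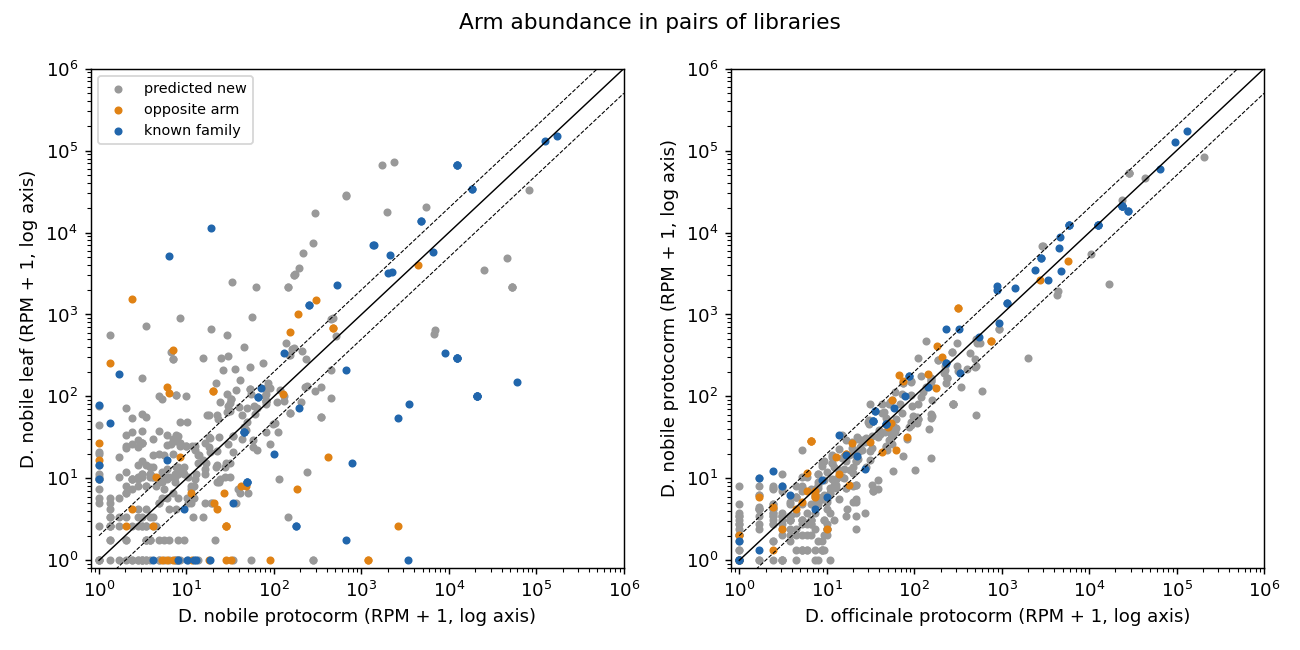
RPM + 1 of each of the 461 arms in pairs of libraries on log axes, leaf against D. nobile protocorm on the left and D. nobile against D. officinale protocorm on the right. The solid line marks equal values and the dashed lines 2-fold differences. Across arms the log values had a Pearson correlation of 0.65 on the left and 0.95 on the right.

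The protocorms of the 2 species were compared at the same culture age. Their known families were close: 17 of 20 families above the minimum were within the rule, 3 were higher in D. nobile and 0 were lower. The 3 were miR390 (2.09-fold, 1.81 to 2.41), which acts in the auxin pathway, miR396 (2.03-fold, 2.00 to 2.05) and miR529 (2.03-fold, 1.83 to 2.25). Each lies at the edge of the rule, and none passed it when the most abundant new arm was left out of the totals. miR396 also failed it with identical members counted once. miR528 (1.92-fold, 1.87 to 1.97) and miR168 (1.88-fold, 1.84 to 1.92) came next, and both passed the rule under TMM scaling. miR156 was at 165039 RPM in D. nobile and 182683 RPM in D. officinale, and the sign of its log2 ratio of -0.15 changed with the scaling. miR319 and miR160 behaved likewise, at log2 ratios of -0.06 and -0.07. miR8175, the suspected fragment entry, had the lowest log2 ratio at -0.80, followed by miR162 at -0.60 and miR157 at -0.36.

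By list, the medians in this comparison were small. With the percentiles among matched lists and among sets of known families, age and phase change had a median of 0.19 (67.7 and 28.0), the auxin pathway 0.49 (87.6 and 66.9), organ growth and polarity 0.39 (82.0 and 44.8), the copper-responsive families 0.74 (88.1 and 86.6), the nutrient-responsive families 0.48 (85.02 and 63.9) and the silencing families 0.16 (58.6 and 30.3). Across all known arms the log values of the 2 protocorm libraries had a Pearson correlation of 0.99, against 0.58 between the leaf and the D. nobile protocorm. Arms are not independent replicates. As single arms, 11 known arms were higher in D. nobile and 1 was lower of 54. den_miR317-5p of miR528, a 16 nt arm, led at 11.3 against 1.40 RPM, which is under the 2.11 RPM of 3 reads in D. officinale. den_miR85-3p of miR171 followed, at 664 against 231 RPM. The lower one was den_miR160-5p, a member of miR171, at 12.0 against 26.7 RPM. With TMM scaling, which shifted all ratios by 0.26, 17 arms were higher and 0 lower.

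The predicted new arms went the other way: 8 were higher in D. nobile and 51 lower among 192 above the minimum. The most abundant new arm of both protocorms, den_miR149-3p (GCAUGCGUGUCGGGACCCGA), took 82596 RPM in D. nobile and 203527 RPM in D. officinale, a 2.46-fold difference. Its precursor lies on NW_018299324.1 at 483 to 567, minus strand, with a score of 2.80. den_miR7-5p had the lowest log2 ratio, -3.15, at 1.41 RPM in D. nobile against 20.4 RPM. Its D. nobile value is close to the 1.06 RPM of 3 reads. den_miR126-5p was 9.27-fold lower in D. nobile, at 16.9 against 156 RPM, and den_miR52-5p was 8.66-fold lower, at 58.4 against 506 RPM. den_miR95-5p was 3.46-fold higher (2.97 to 4.04) and den_miR168-5p 5.10-fold higher (2.21 to 14.4). These counts depend on the scaling: with TMM 22 new arms were higher in D. nobile and 38 lower, and with median-of-ratios 29 were higher and 36 lower.

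The leaf of D. nobile and the protocorm of D. officinale differ in both tissue and species, so only values are given. Of the families, 7 were higher in the leaf, 9 were lower and 5 were within the rule. miR399 was 919-fold higher (627 to 1407), miR396 10.9-fold higher (10.8 to 11.1), miR167 6.13-fold higher, miR168 4.58-fold higher and miR172 97.4-fold higher (16.98 to 3883). miR156 was 278-fold lower (260 to 298), miR529 414-fold lower (73.7 to 16322), miR390 54.5-fold lower (21.1 to 202), miR319 46.9-fold lower and miR397 29.9-fold lower. miR171 was lower at a log2 ratio of -2.41 as a sum and -5.93 for its most abundant member alone. miR164 was within the rule at 0.44 as a sum, and lower at -1.95 for its most abundant member alone. Of known arms 23 were higher and 26 lower, and of new arms 107 were higher and 72 lower. The age and phase change list had a median log2 ratio of -5.95 at the 0.045 percentile of matched lists and the 0.376 percentile of known families. It again counts the related miR156, miR157 and miR529 as separate families. The copper-responsive list had -4.34 at the 0.795 and 11.7 percentiles and the nutrient-responsive list 5.83 at the 97.7 and 97.4 percentiles.

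Most arms were found in every library. Of the 65 known arms, 62 had a read in the D. nobile protocorm, 58 in the leaf and 61 in the D. officinale protocorm, and 54 in all 3. There were 7 known arms with reads in both protocorms and none in the leaf, and 3 with reads in the leaf alone. Of the 353 new arms 292 had a read in all 3 libraries, and 168 had at least 10 reads in each. Thinned to the depth of the leaf library, 53 known and 281 new arms were found in all 3.

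The predicted precursors differed from those of known families. The 65 precursors with a known arm had a median length of 85 nt and a median folding energy of -38.9 kcal/mol, against 63 nt and -17.4 kcal/mol for the 319 others. The median predictor score was 369 for the known and 2.20 for the new precursors, and 70 of the 319 new precursors reached a score of 5. Star reads were present for 48 of 65 known and 82 of 319 new precursors. Of the new precursors 317 had an arm in the expression table, as did all 65 known ones. The most abundant listed arm began with U in 80.0% of the 65 and in 29.3% of the 317. It had 24 nt in 32.8% and 15 to 17 nt in 43.5% of the 317, whereas it had 21 nt in 60.0% of the 65. Known arms were picked by their match to canonical sequences, so their first base and length follow in part from that choice.

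**Figure D3:**
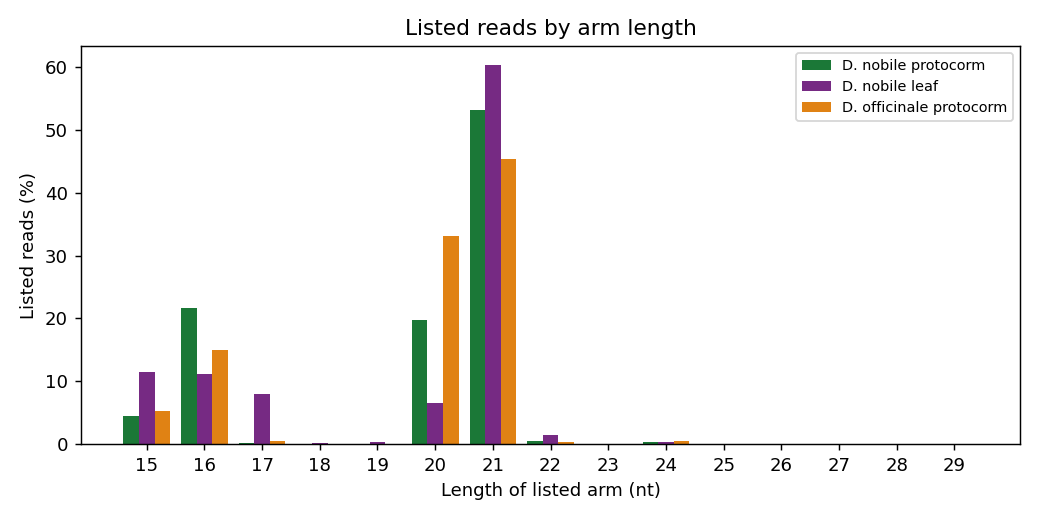
Share of listed reads in percent by arm length in nt, with 1 bar per library. Arms of 20 to 22 nt held 73.2%, 68.4% and 78.7% of reads in the D. nobile protocorm, the leaf and the D. officinale protocorm, and arms of 15 to 17 nt held 26.4%, 30.6% and 20.7%.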

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

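The tests in this part were all chosen after the result was seen. With 1 library per group, no library could be set against others of its group, and no difference between groups could be tested. The loop reads of the predictor's table, pooled over the libraries, were not used in the comparisons. They exceeded the 3 reads that a count of 0 allows in 58 of 384 precursors. The precursor of den_miR149-3p had the most, 9475 loop reads of 788404 reads in total, or 1.20%, against 3343 star reads.

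Predicted new arms of 15 to 17 nt held 26.4%, 30.6% and 20.7% of reads. A candidate explanation is that these are fragments of tRNA 5′ ends. Of the 116 distinct sequences of these short arms, 8 (6.90%) lay within 3 mismatches of 9 hand-written tRNA 5′ ends, against 0.0862% of the same sequences shuffled. Matching arms held 88.5% of the short arms' reads in the D. nobile protocorm, 83.3% in the D. officinale protocorm and 34.0% in the leaf, but arms with 0 or 1 mismatch held only 28.3%, 41.8% and 31.8%. These shares list nearly the same reads for each of den_miR221-5p, den_miR304-3p and den_miR370-3p, near 52690 RPM each in the D. nobile protocorm. All have 3 mismatches, so counting copies once would raise the protocorm shares with 0 or 1 mismatch. Those shares were not computed that way. With copies counted once, arms that match tRNA-Ala summed to 124964 RPM in the D. nobile protocorm and 96379 RPM in the D. officinale protocorm. Of these, den_miR59-3p (1 mismatch) had 46452 and 43918 RPM, and den_miR92-3p (0 mismatches) had 25240 and 23520 RPM. den_miR221-5p (3 mismatches) had 52690 and 28365 RPM. The explanation is left open for most short reads of the leaf, and in the protocorms for a part whose size was not computed. Counting of other sequences with mismatches is also open for the short arms as a class. By medians, the ratio of table reads to predictor mature reads was 1.20 times higher for short arms than for arms of 20 to 24 nt (bootstrap interval 1.06 to 1.42). This is under the 3 times set as needed, but the ratio exceeded 10 in 8.70% of short arms and 0.617% of arms of 20 to 24 nt. den_miR221-5p and den_miR304-3p differ in sequence but have nearly the same reads in each library, so the same reads were probably counted for both. No biological explanation was tested.

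In the leaf miR156 was lower and miR172 higher than in the D. nobile protocorm. Over 5 scalings the lowest absolute log2 ratio of both was 5.23. TMM and median-of-ratios scaling shifted all ratios by only -0.38 and -0.70, so this outcome was close to fixed in advance and decides little. A scaling moves both families the same way, which argues against scaling as the whole cause of opposite differences. For miR156 alone, reads shared between copies are argued against by its opposite arms, which are other reads. They were 700.0-fold lower in the leaf (340 to 1741) with each distinct sequence counted once, and 917-fold (445 to 2281) over all listed copies. miR172 was not put to this test. Organ, plant age and culture on hormone medium all differ between these libraries, so that a biological difference stays a hypothesis that may rest on any of them, and none was tested.

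In the D. nobile against the D. officinale protocorm, 51 new arms were lower and 8 higher of 192, while 11 known arms were higher and 1 lower of 54. Most arms of both classes were within the rule. Scaling moves both classes alike, and the difference of their medians over distinct sequences was -0.62 (bootstrap interval -1.01 to -0.22), which argues against scaling as the whole cause. Reads of D. nobile could be lost where its sequence differs from the reference used for prediction. Opposite arms, less conserved than matching arms, differed from them by a median of -0.23 over 23 pairs (-0.71 to 0.12), too wide to decide. A difference between the species was not tested and stays open.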

How the results depend on the processing

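No paired analysis was possible because each group has 1 library. Chosen after seeing the data were the count rule, near-identical counts, arms under 18 nt, the total without the most abundant new arm, the list percentiles among known families, and for new arms also the TMM, median-of-ratios and family totals, the log2 ratio of 2 and the pseudocounts. Scaling to known and new reads together equals the setting reported. No called family changed direction, and miR8175 has no value without arms under 18 nt. The cause of each change below was not tested beyond what its setting removes.

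Leaf against D. nobile protocorm: 14 of 16 called families kept their call in every alternative that gave a value, all but miR168 and miR827. Known arms lower (28) became 18 with identical sequences and 18 with near-identical counts counted once. New arms higher (118) became 77 at a log2 ratio of 2, 36 and 25 at scores of 5 and 10, 61 under the count rule and 63 without arms under 18 nt. New arms lower (51) became 82 without a minimum, 24 at a log2 ratio of 2, 12 and 2 at scores of 5 and 10, 27 under the count rule and 20 without arms under 18 nt.

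D. nobile against D. officinale protocorm: 0 of 3 called families kept their call throughout. miR396 lost its call also with identical members counted once. Families higher (3) became 5 with TMM, 6 with median-of-ratios, 5 without the most abundant family, 5 without arms under 18 nt and 0 without the most abundant new arm, where 1 was lower. Known arms higher (11) became 17 with TMM and 17 with median-of-ratios, 4 without the most abundant new arm, 7 and 7 with identical and near-identical arms counted once, 1 at a log2 ratio of 2, 6 at a pseudocount of 10 and 6 under the count rule. Known arms lower (1) became 2 without the most abundant new arm and 0 with TMM, median-of-ratios, the total without the most abundant family, a log2 ratio of 2, a pseudocount of 10, the count rule, or no arms under 18 nt. New arms higher (8) became 22 with TMM, 29 with median-of-ratios, 15 without the most abundant family, 20 with the total of new arms, 39 without a minimum, 24 at 10 reads, 1 at a log2 ratio of 2, 2 and 0 at scores of 5 and 10, and 5 under the count rule. New arms lower (51) became 95 without a minimum, 18 at a log2 ratio of 2, 12 and 7 at scores of 5 and 10, 23 under the count rule and 24 without arms under 18 nt.

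Leaf against D. officinale protocorm: 16 of 16 called families kept their call. Here too no alternative counted den_miR74-3p in miR159, which would remove the miR159 call. That arm had 4781 RPM in the D. officinale protocorm and no read in the leaf, where miR159 had 2934 RPM. Known arms lower (26) became 16 with identical and 16 with near-identical arms counted once. New arms higher (107) became 31 and 21 at scores of 5 and 10, 60 under the count rule and 63 without arms under 18 nt. New arms lower (72) became 111 without a minimum, 41 at a log2 ratio of 2, 19 and 5 at scores of 5 and 10, 45 under the count rule and 32 without arms under 18 nt.

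New arms in all 3 libraries (292) became 168 at 10 reads. The miR166 share became 27.1%, 23.6% and 19.03% with identical sequences counted once, as a share of totals that were also counted this way. Of the 317 new precursors with a listed arm, those with a 24 nt arm (32.8%) became 25.7% and 27.3% at scores of 5 and 10, and those with an arm of 15 to 17 nt (43.5%) became 24.2% at a score of 10. Depth limits the low families: miR172 had 1 read in each protocorm library and miR529 1 read in the leaf.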

Other observations

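All tests and groupings in this part were chosen after the values were seen. The short arms that match tRNA 5′ ends fell into 2 groups. The 8 arms that match tRNA-Ala summed to 230689 RPM in the D. nobile protocorm, 153355 RPM in the D. officinale protocorm and 15046 RPM in the leaf. Of these, 5 arms have 3 mismatches and carry 158761, 85608 and 6657 RPM. The 3 arms that match the plastid trnH-GUG summed to 88999 RPM in the leaf, 18684 RPM in the D. officinale protocorm and 2639 RPM in the D. nobile protocorm. den_miR330-3p (GCGGAUGUAGCCAAG), the most abundant new arm of the leaf at 71677 RPM, matches trnH-GUG with 0 mismatches. Several of these arms have the same sequence or nearly the same reads. With such copies counted once, 5 tRNA-Ala arms summed to 124964 RPM in the D. nobile protocorm, 96379 RPM in the D. officinale protocorm and 10627 RPM in the leaf, and 2 trnH-GUG arms to 2349, 16707 and 71769 RPM. The matching arms then held 85.7%, 33.7% and 79.5% of the short arms' reads in the D. nobile protocorm, the leaf and the D. officinale protocorm.

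New precursors whose most abundant arm has 24 nt numbered 104. That arm began with A in 61.5% and with U in 17.3% of them, against 18.9% and 58.5% of the 53 new precursors with an arm of 20 to 22 nt. All new arms of 23 nt or more held 0.311% of reads in the D. nobile protocorm, 0.446% in the leaf and 0.484% in the D. officinale protocorm.

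den_miR74-3p had reads for 3421 RPM in the D. nobile protocorm and 4781 RPM in the D. officinale protocorm, while the predictor's table gives 24 mature reads for its precursor over all libraries.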
